A study of Mus musculus with 4 samples.

How the data were processed

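The series measured histone H4 acetylation by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse bone marrow-derived macrophages, primary cells grown from C57BL/6 marrow and taken on day 7 of differentiation. The antibody recognised acetylated histone H4. The 4 libraries crossed genotype with treatment. Cells were HDAC3 +/-, which the submitters call wild type (wt), or HDAC3 -/- (HDAC3 KO), and were left untreated or treated for 4 h with 100 ng/ml lipopolysaccharide (LPS). Each of the 4 groups had 1 library, so no spread between replicates could be measured, no p-value across conditions was computed and no library could be left out in turn.

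Per the submitters' processing notes, Bowtie and the mm9 mouse genome build were used. Peaks were called with MACS for each ChIP library against an input library, per the file headers. The versions and settings of these programs, and which input library served which ChIP library, were not given in the sources used here. Per the labels, each list belongs to 1 library, so peaks were called per library and not on pooled reads. Each list gave a start, an end and a score for every peak. The score is the authors' own value for that peak, as deposited, with a lowest value near 50 in every list. Its scale is not stated, and it depends on read depth and on the input. It was therefore used mainly to describe, rank or filter peaks within a list. Counts of peaks or regions at or above a fixed score were also set side by side between lists. Such counts depend on depth and input too. Peaks within a list did not overlap each other. The files hold peak positions and scores, not reads, so read depth per library is unknown. The number of peaks and the length they cover describe what was called and cannot be separated here from depth or from the efficiency of the immunoprecipitation.

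A peak was counted as shared when at least 1 bp overlapped a peak of the other list, with bedtools 2.31.1. The share of peaks without such an overlap was given with an exact (Clopper-Pearson) 95% interval from scipy 1.17.1. Neighbouring peaks are not independent, so these intervals cover counting error only. As a chance level, the peaks of a list were placed at random along the same chromosomes 20 times, over the span that peaks occupied, and compared with the other list. For the crossed design, overlapping peaks of the 4 lists were merged into regions, and each region was described by the lists with a peak in it. A region with a peak in LPS-treated and none in untreated cells of a genotype is called gained, and the opposite is called lost. These words describe calls in a pair of libraries and carry no test. For the crossed shares, a reference share was computed over regions with a peak in both wt libraries, weighted to the same score deciles. Covered length was also summed in 50-kb windows. Coordinates are mm9, counted from 1.

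Regions named by the fixed rule were, for each comparison and direction, the 5 peaks with the highest score that had no peak of the other library within 5000 bp, with ties ordered by width and then position. This rule, the comparisons and the alternative settings were fixed before the data were examined. Other regions and windows that are named were chosen after their values were seen, and the text says so. The alternative settings were peaks at or above each list's median score, the 20000 highest-scored peaks of each list, an overlap of at least 50% of the peak, peaks within 500 bp counted as shared, regions merged across gaps of up to 500 bp, and chromosomes without X, Y, mitochondrial and unplaced sequences.

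The plan also held counts of genes with a promoter peak and 15 gene lists for use with an mm9 gene annotation. The gene table used here is on GRCm38, another build, and coordinates were not converted. Promoter counts and gene lists were therefore not run, no gene name is attached to any region, and the Hdac3 locus itself was not examined as a check of the labels. The overlap and pattern counts were tested on simulated lists with known answers: 22 of 22 counts were recovered exactly over 57684 simulated regions, 200 of them seeded as gained in both genotypes. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.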

Results

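Histone H4 acetylation marks active promoters and enhancers, and HDAC3 is a histone deacetylase that works within corepressor complexes. The series asked what HDAC3 contributes to the inflammatory gene expression program of macrophages, and acetylated H4 was mapped genome-wide in wt (HDAC3 +/-) and HDAC3 KO (HDAC3 -/-) bone marrow-derived macrophages. LPS, a component of the outer membrane of Gram-negative bacteria, was given for 4 h at 100 ng/ml. Each of the 4 groups had 1 library, so the differences given here are between libraries and cannot be set against a spread between replicates.

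The lists held 48706 peaks in untreated wt, 39550 in LPS-treated wt, 41956 in untreated HDAC3 KO and 45589 in LPS-treated HDAC3 KO. They covered 35.4, 37.4, 36.5 and 50.4 Mb in the same order, with median peak widths of 590.0, 722, 691 and 836 bp. Read depth was unknown. The score of a peak is the authors' own value, and it is not comparable between lists. A total of 983 peaks (2.02%, interval 1.90 to 2.15%) lay on the X chromosome in untreated wt, 919 (2.32%, 2.18 to 2.48%) in LPS-treated wt, 851 (2.03%, 1.90 to 2.17%) in untreated HDAC3 KO and 958 (2.10%, 1.97 to 2.24%) in LPS-treated HDAC3 KO. No peak was listed on the Y chromosome in any library.

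**Figure D1:**
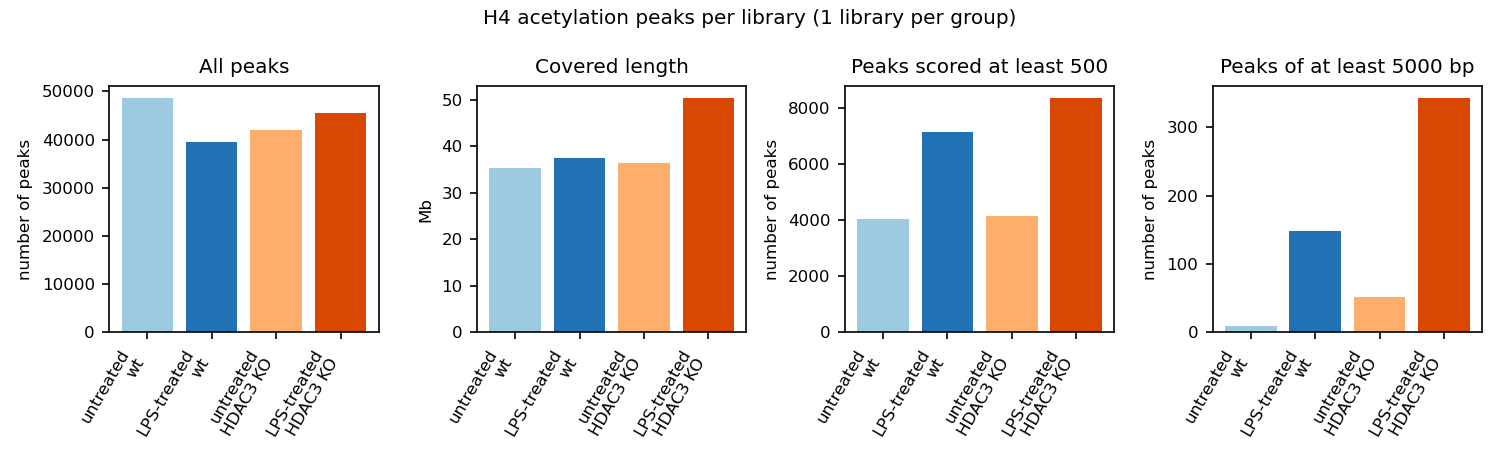
Bars give, for each of the 4 libraries on the x axis, the number of peaks, the length they cover in Mb, the number of peaks scored at least 500 and the number at least 5000 bp wide. The list of untreated wt was the longest at 48706 peaks, whereas LPS-treated HDAC3 KO covered the greatest length at 50.4 Mb and had the most peaks of at least 5000 bp, 343.

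The first comparison asked where LPS changed the acetylation calls in wt macrophages. The highest-scored region with a peak in LPS-treated and none near it in untreated wt lay at chromosome 18, 75069246 to 75073300, with a score of 3199.6. A second such region lay on the same chromosome at 75054206 to 75057789. The others were chromosome 6, 38291539 to 38294208, chromosome 7, 81836527 to 81843394, and chromosome 10, 75171472 to 75174533. All 5 had a peak in LPS-treated HDAC3 KO as well, and none had a peak in untreated HDAC3 KO.

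In the other direction, the highest-scored region with a peak in untreated and none near it in LPS-treated wt lay at chromosome 4, 109077983 to 109080259 (score 1136). It was followed by chromosome 15, 58576599 to 58580442 (936), chromosome 6, 99337428 to 99340235 (853), chromosome 8, 28017558 to 28019011 (777), and chromosome 13, 52059062 to 52060642 (739). All 5 had a peak in untreated HDAC3 KO, and 4 of the 5 also had a peak in LPS-treated HDAC3 KO. The exception was the chromosome 4 region.

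Of the 39550 peaks in LPS-treated wt, 12546 (31.7%, interval 31.3 to 32.2%) had no overlapping peak in untreated wt. Of the 48706 peaks in untreated wt, 17333 (35.6%, 35.2 to 36.0%) had none in LPS-treated wt. With positions placed at random these shares were 97.2 and 97.5%. Peaks without a partner were the weaker part of each list: in LPS-treated wt their median score was 81.9 against 208 for shared peaks, and in untreated wt 74.1 against 171. Among the 10% of peaks with the highest scores, 4.98% in LPS-treated and 2.01% in untreated wt lacked a partner. Peaks scored at least 500 with no peak of the other library within 5 kb numbered 235 in LPS-treated and 36 in untreated wt. The larger share in untreated wt depended on the number of peaks used: with the 20000 highest-scored peaks of each list it was 28.6%, against 34.9% in LPS-treated wt.

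**Figure D2:**
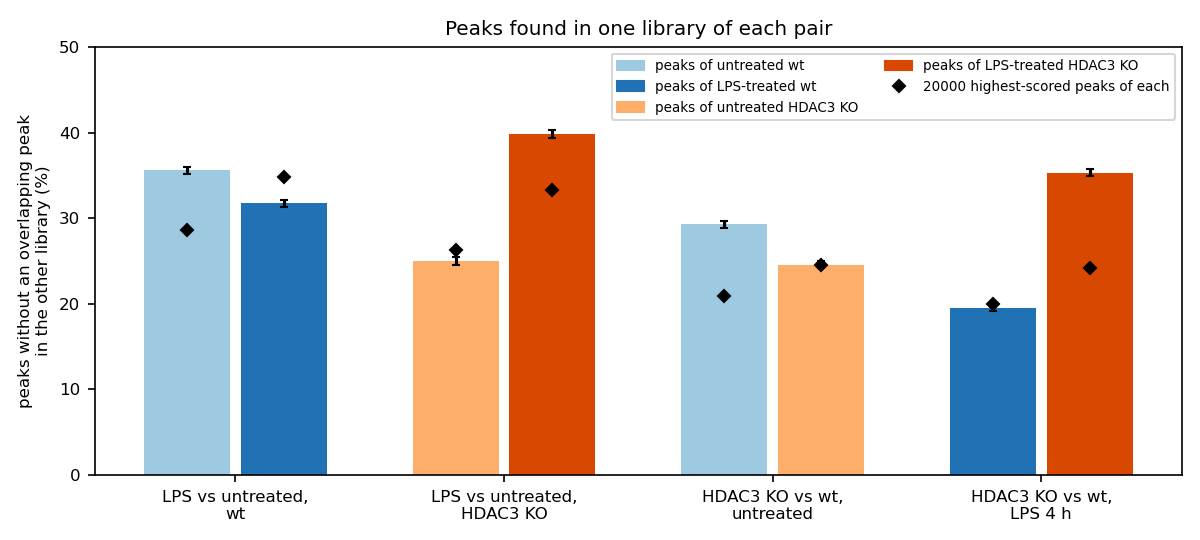
Bars give the percent of the peaks of each library, named by colour, without an overlapping peak in the other library of the pair on the x axis, error bars are exact 95% intervals for counting error, and diamonds give the same share with the 20000 highest-scored peaks of each list. With all peaks the share was higher in the untreated library for wt (35.6 against 31.7%) and in the LPS-treated library for HDAC3 KO (39.9 against 25.0%), and the diamonds turn the order for wt (28.6 against 34.9%) and for untreated HDAC3 KO against wt.

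The second comparison asked the same of HDAC3 KO macrophages. The highest-scored regions with a peak in LPS-treated and none near it in untreated HDAC3 KO lay at chromosome 11, 82928864 to 82934117, chromosome 16, 97682051 to 97687227, chromosome 2, 30767517 to 30772028, and chromosome 7, 152174429 to 152177948, each with a score of 3100, the value at which many of the highest scores were tied. The last of the 5 was chromosome 6, 38291386 to 38294273 (2998), which overlaps a region named in wt. All 5 had a peak in LPS-treated wt, and 4 of the 5 had a small peak in untreated wt, with scores of 54.2 to 247 covering 423 to 1258 bp.

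The highest-scored region with a peak in untreated and none near it in LPS-treated HDAC3 KO lay at chromosome 8, 85579116 to 85579951 (score 901). The others were chromosome 8, 13500532 to 13503897 (871), chromosome 1, 88931051 to 88933696 (792), chromosome 6, 117380728 to 117382999 (750.0), and chromosome 2, 29594030 to 29595996 (728). All 5 had a peak in untreated wt. The chromosome 6 and chromosome 2 regions also had a peak in LPS-treated wt, with scores of 90.0 and 148 in that list.

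In LPS-treated HDAC3 KO, 18171 of 45589 peaks (39.9%, interval 39.4 to 40.3%) had no partner in untreated HDAC3 KO. In the untreated library, 10491 of 41956 (25.0%, 24.6 to 25.4%) had none in LPS-treated HDAC3 KO. The shares with positions placed at random were 97.1 and 96.7%. The order was the same with the 20000 highest-scored peaks of each list, at 33.3 and 26.3%. Peaks scored at least 500 with no peak of the other library within 5 kb numbered 406 in LPS-treated and 20 in untreated HDAC3 KO. Median scores were 85.1 for unpaired and 244 for shared peaks in LPS-treated HDAC3 KO.

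Peak number changed with LPS by -18.8% in wt and by 8.66% in HDAC3 KO, while covered length changed by 5.77 and 38.4% and median width by 22.4 and 21.0%. Among peaks scored at least 500, the number went from 4046 to 7139 in wt and from 4150 to 8359 in HDAC3 KO. Among those scored at least 1000 it went from 708 to 2803 and from 823 to 3284. A score depends on depth, so these counts describe the lists and not the amount of acetylation.

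The third comparison asked whether the loss of HDAC3 changed acetylation calls before stimulation. The highest-scored regions with a peak in untreated HDAC3 KO and none near it in untreated wt lay at chromosome 6, 55225191 to 55227095 (score 1123), chromosome 7, 105531784 to 105534729 (1082), chromosome 17, 33061167 to 33062739 (1074), chromosome 2, 127349068 to 127350370 (809), and chromosome 2, 158131578 to 158132896 (752). All 5 also had a peak in LPS-treated HDAC3 KO and none in LPS-treated wt. The score in LPS-treated HDAC3 KO was 1324 at the chromosome 17 region and 74.3 at the chromosome 6 region.

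Regions with a peak in untreated wt and none near it in untreated HDAC3 KO were led by chromosome 6, 124946762 to 124949111 (873). They were followed by chromosome 6, 48486825 to 48488337 (785), chromosome 14, 56433367 to 56435088 (721), chromosome 16, 10383694 to 10384937 (634), and chromosome 15, 12596812 to 12598586 (579). All 5 had a peak in LPS-treated wt and none in LPS-treated HDAC3 KO. In both directions, then, each of the 5 named regions had the same genotype difference in calls in LPS-treated cells, which were separate libraries. These were the highest-scored regions. Of all merged regions called in HDAC3 KO alone when untreated, 1752 of 8177 kept that difference with LPS. For those called in wt alone it was 1260 of 11919. The labels give no batch, so whether libraries of a genotype shared a preparation is unknown.

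In untreated HDAC3 KO, 10314 of 41956 peaks (24.6%, interval 24.2 to 25.0%) had no partner in untreated wt, and in untreated wt 14271 of 48706 (29.3%, 28.9 to 29.7%) had none in untreated HDAC3 KO. With positions placed at random these shares were 97.3 and 97.5%. With the 20000 highest-scored peaks of each list the order turned, at 24.5% in HDAC3 KO and 20.9% in wt. Only 14 peaks of untreated HDAC3 KO and 7 of untreated wt scored at least 500 and had no peak of the other library within 5 kb. Among the 10% of peaks with the highest scores, 0.52% in HDAC3 KO and 0.43% in wt lacked a partner. Peak number differed by -13.9% (HDAC3 KO against wt), covered length by 2.99% and median width by 17.1%.

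The fourth comparison asked how LPS-treated HDAC3 KO differed from LPS-treated wt. The highest-scored regions with a peak in HDAC3 KO and none near it in wt lay at chromosome 10, 24627799 to 24631243 (score 1807), chromosome 11, 31720067 to 31724064 (1718), chromosome 1, 174519271 to 174521966 (1695), chromosome 8, 124315304 to 124317770 (1649), and chromosome 10, 92511191 to 92513241 (1614). Of these 5, 4 had a peak in untreated HDAC3 KO and 3 in untreated wt. The second chromosome 10 region had a peak in no other library.

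Regions with a peak in LPS-treated wt and none near it in LPS-treated HDAC3 KO were led by chromosome 4, 124467406 to 124469633 (1973), which had a peak in no other library. They were followed by chromosome 15, 12596745 to 12598651 (1439.7), chromosome 6, 124946787 to 124948483 (952), chromosome 2, 10899955 to 10902311 (885), and chromosome 15, 79006835 to 79008550 (869). None of the 5 had a peak in untreated HDAC3 KO. The first chromosome 15 region and the chromosome 6 region had a peak in untreated wt and are also named in the third comparison.

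In LPS-treated HDAC3 KO, 16101 of 45589 peaks (35.3%, interval 34.9 to 35.8%) had no partner in LPS-treated wt, against 7730 of 39550 (19.5%, 19.2 to 19.9%) in the other direction. With positions placed at random these shares were 97.2 and 96.6%. With the 20000 highest-scored peaks of each list they were 24.2 and 20.0%, in the same order but closer. Peaks scored at least 500 and clear of the other library by 5 kb numbered 120 in HDAC3 KO and 21 in wt. Peak number differed by 15.3% (HDAC3 KO against wt), covered length by 34.8% and median width by 15.8%.

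The crossed design asked whether regions gained or lost with LPS in wt had the same calls in HDAC3 KO. Merging the 4 lists gave 62481 regions, of which 17827 (28.5%) had a peak in all 4 libraries. A peak in both LPS-treated libraries and neither untreated library was found in 4101 regions, and the reverse in 3036. A peak in both HDAC3 KO libraries and neither wt library was found in 1752 regions, and the reverse in 1260. Regions gained in wt and lost in HDAC3 KO numbered 289, and regions lost in wt and gained in HDAC3 KO numbered 1166. Where every peak present scored at least 200, these numbers were 629, 101, 60, 30, 0 and 2 in the same order.

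**Figure D3:**
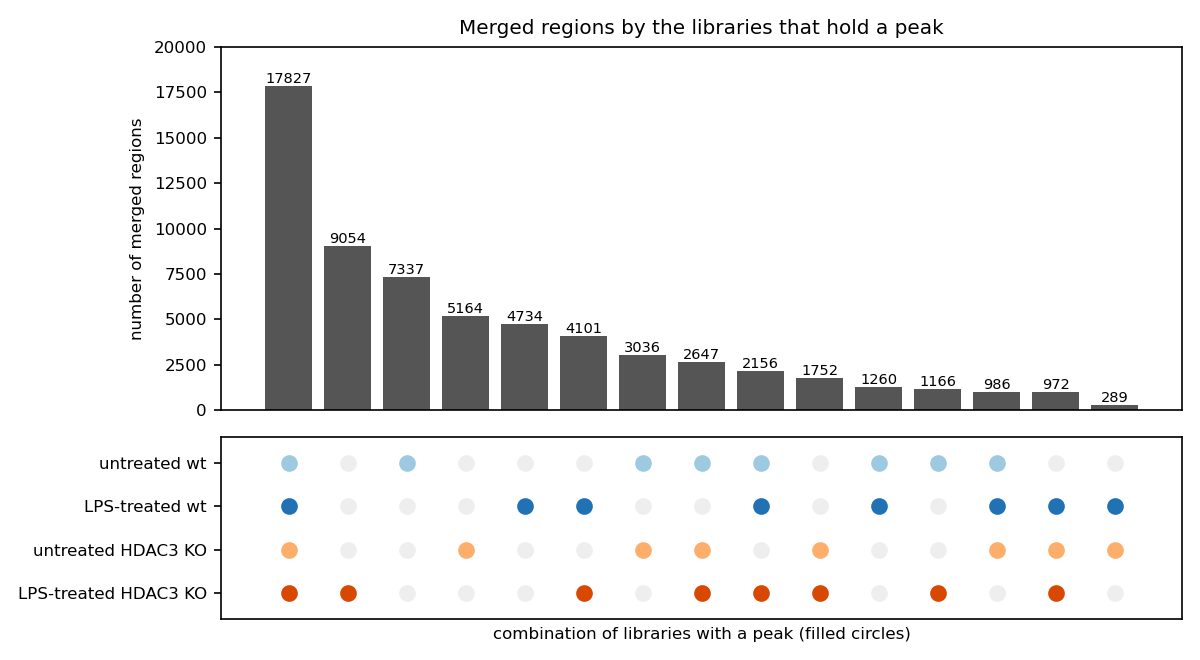
Bars give the number of merged regions for each combination of libraries with a peak, marked by the filled circles under the bar. The combination of all 4 libraries held 17827 regions, the combination of both LPS-treated libraries 4101 and the combination of LPS-treated wt with untreated HDAC3 KO 289.

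Of the 10096 regions gained in wt, 5073 (50.3%, interval 49.3 to 51.2%) had a peak in LPS-treated HDAC3 KO, against a score-matched reference of 76.4% among regions called in both wt libraries. In untreated HDAC3 KO, 1261 of them (12.5%, 11.9 to 13.2%) had a peak, against a reference of 74.0%. Of the 14186 regions lost in wt, 10373 (73.1%, 72.4 to 73.9%) lacked a peak in LPS-treated HDAC3 KO, against a reference of 21.4%. Most of these 10373 had no peak in untreated HDAC3 KO either: 7337 regions were called in untreated wt alone, and 3036 (21.4% of the regions lost in wt, 20.7 to 22.1%) were lost in HDAC3 KO too. A peak in untreated HDAC3 KO was found in 40.1% (39.3 to 40.9%) of the regions lost in wt. Under stricter calls, chosen after seeing the data, with a peak present only at or above the median score and absent only where no peak was listed, 69.6% of the gained regions had a peak in LPS-treated and 4.06% in untreated HDAC3 KO, and 77.0% of the lost regions lacked a peak in LPS-treated HDAC3 KO. Gained and lost regions were chosen by their calls in untreated and LPS-treated wt, so a call missed in either wt library enters every one of these shares.

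The 4101 regions gained in both genotypes compared with 2662 if gains in the genotypes were independent over the merged regions, a ratio of 1.54, and for the 3036 lost in both the ratio was 1.41. The opposite combinations had ratios of 0.19 for the 289 regions and 0.31 for the 1166. For genotype, the 1752 regions called in HDAC3 KO alone under both treatments compared with 1913 (ratio 0.92) and the 1260 called in wt alone with 1387 (0.91), so neither exceeded the number for independent calls. The opposite genotype combinations had lower ratios. The ratio was 0.30 for the same 289 regions, called in HDAC3 KO alone when untreated and in wt alone with LPS. For the same 1166 regions, with the reverse calls, it was 0.42. Comparisons of LPS with untreated cells share no library between the genotypes. Merged regions had a peak in at least 1 library by definition, so these expected numbers are a rough guide.

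Single regions illustrate the groups and were chosen after their values were seen, as those with the highest scores in every library with a peak. The region at chromosome 6, 38291386 to 38294273, was scored 3138 in LPS-treated wt and 2998 in LPS-treated HDAC3 KO. The region at chromosome 8, 85579116 to 85580375, was scored 725 in untreated wt and 901 in untreated HDAC3 KO. The region at chromosome 17, 33061069 to 33062935, was scored 1074 in untreated and 1324 in LPS-treated HDAC3 KO. The region at chromosome 6, 124946762 to 124949111, was scored 873 in untreated and 952 in LPS-treated wt.

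**Figure D4:**
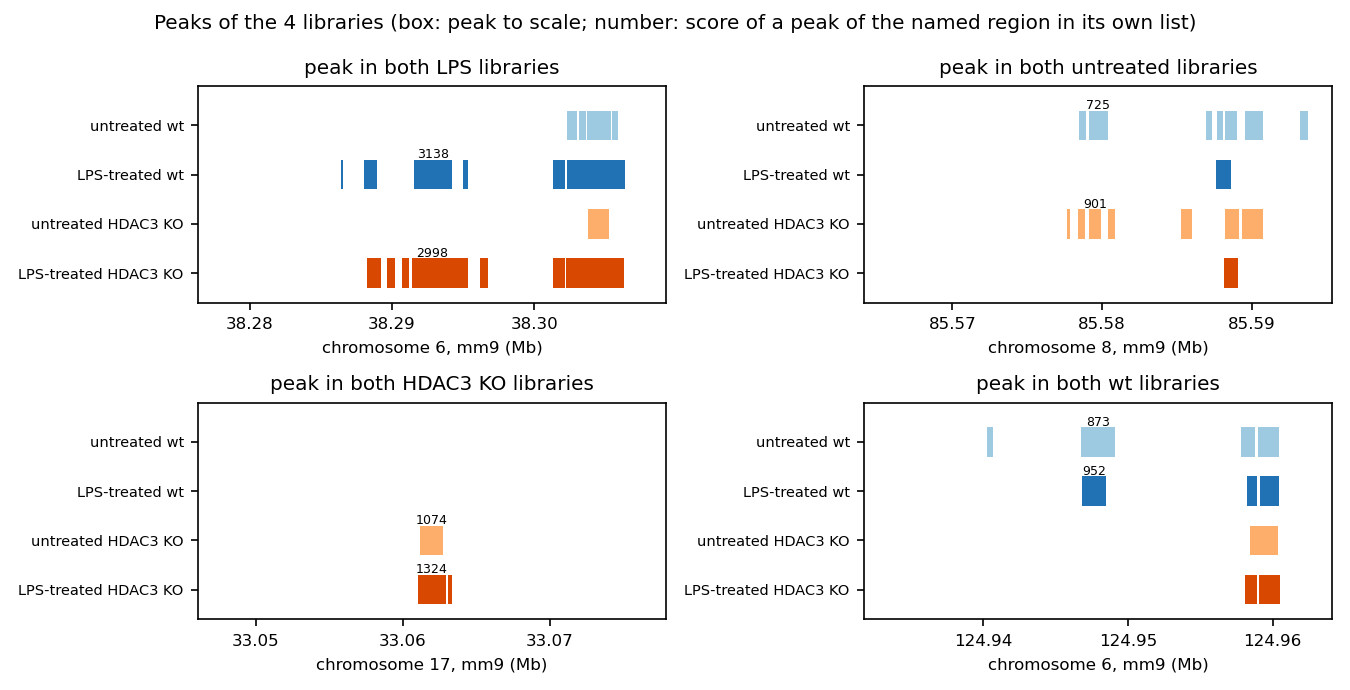
Each panel maps the peaks of the 4 libraries (boxes to scale, 1 library per line) around a region against mm9 position in Mb, with the score of each peak of that region in its own list above it. Peaks stood in both LPS-treated libraries on chromosome 6 (3138 and 2998), in both untreated libraries on chromosome 8 (725 and 901), in both HDAC3 KO libraries on chromosome 17 (1074 and 1324) and in both wt libraries on chromosome 6 (873 and 952).

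Covered length per 50-kb window gave a view of longer acetylated domains. These windows were examined and named after the data were seen. In the window at chromosome 11, 81800001 to 81850000, peaks covered 11.1 kb in untreated and 33.6 kb in LPS-treated wt, and 11.7 and 36.9 kb in HDAC3 KO. In the window at chromosome 17, 18000001 to 18050000, they covered 9.20 and 31.5 kb in wt and 4.12 and 34.0 kb in HDAC3 KO. In the window at chromosome 16, 24600001 to 24650000, they covered 3.47 and 22.1 kb in wt and 3.77 and 24.3 kb in HDAC3 KO. The window at chromosome 12, 80700001 to 80750000, went the other way, from 10.3 to 1.60 kb in wt and from 13.5 to 4.01 kb in HDAC3 KO.

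Across the 17547 windows with a peak in any library, the LPS change in covered length had a Pearson r of 0.67 and a Spearman rho of 0.49 between the genotypes. For comparison, the genotype change in covered length had a Pearson r of 0.41 between untreated and LPS-treated cells. These are correlations across windows, which are not independent replicates. A gain of at least 5 kb in both genotypes was found in 297 windows and a loss of at least 5 kb in both in 33. No window gained 5 kb in wt and lost 5 kb in HDAC3 KO, and 2 did the opposite. After each library was divided by its total covered length, an alternative chosen after seeing the data, the numbers were 192 gains and 80 losses in both genotypes.

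**Figure D5:**
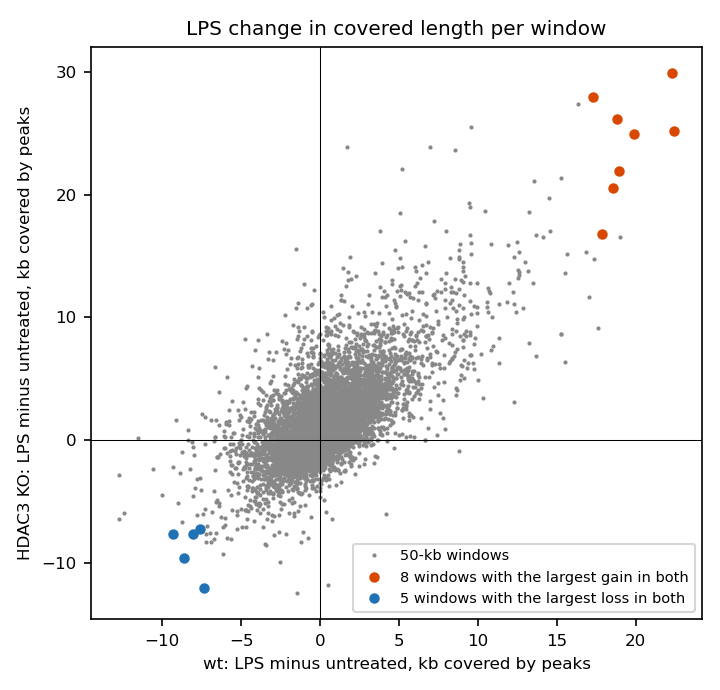
Each point is a 50-kb window, with the LPS minus untreated difference in kb covered by peaks in wt on the x axis and in HDAC3 KO on the y axis. The 8 windows with the largest gains in both genotypes (orange) and the 5 with the largest losses in both (blue) were chosen after the data were seen, and Pearson's r across the 17547 windows was 0.67.

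Chosen in the same way, the window with the largest LPS change in HDAC3 KO over that in wt was chromosome 10, 18650001 to 18700000, and the window with the largest in wt over that in HDAC3 KO was chromosome 2, 167750001 to 167800000. In the first, covered length went from 1.92 to 3.65 kb in wt and from 5.34 to 29.2 kb in HDAC3 KO. In the second it went from 10.3 to 10.8 kb in wt and from 19.4 to 7.59 kb in HDAC3 KO. After division by total covered length the change in wt in this second window was -0.13 kb. Covered length was greater in HDAC3 KO under both treatments at chromosome 6, 48950001 to 49000000, with 22.5 and 17.6 kb against 8.55 and 2.00 kb in wt. It was greater in wt under both treatments at chromosome 4, 43450001 to 43500000, with 14.3 and 28.0 kb against 9.55 and 16.4 kb in HDAC3 KO. These differences have no replicate check.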

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

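The tests of peak splitting and of low-scored peaks given here were chosen only after the result was seen, as were the windows; the test of usable reads was written down before its result was seen. With 1 library per group, none of the differences between genotypes in this part was tested.

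Peak number moved in opposite directions with LPS, by -18.8% in wt and by 8.66% in HDAC3 KO. Splitting of wide peaks into pieces is argued against as the whole cause, since after peaks within 500 bp were joined the changes were -14.8 and 9.25%, and the genotypes stayed 24.0 percentage points apart (27.5 as deposited). Fewer usable reads in LPS-treated wt is argued against as the sole cause, since in 56.0% of the 17827 regions called in all 4 libraries peaks covered more bp in LPS-treated than in untreated wt (68.1% in HDAC3 KO), although fewer reads together with wider domains after LPS stays open because depth is unknown. A candidate explanation is that the lower number in wt lies in low-scored peaks. Among peaks scored at least 100 the number still changed by -10.3% in wt and by 18.6% in HDAC3 KO. Among those scored at least 200 it changed by 4.52% in wt and by 33.6% in HDAC3 KO. Scores depend on depth too, and the median score was 116 in untreated and 141 in LPS-treated wt (122 and 145 in HDAC3 KO). Counts above a fixed score therefore cannot settle where the lower number lies. A difference in the response of the genotypes stays open and untested.

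Calls moved in opposite directions with LPS in 289 regions that were gained in wt and lost in HDAC3 KO, and in 1166 that were lost in wt and gained in HDAC3 KO. Both numbers were below those for independent calls, 1531 and 3741 (ratios 0.19 and 0.31). Only 0 and 2 of these regions scored at least 200 in each library with a peak. Missed calls stay open as their source. Covered length also moved in opposite directions in 3 of the windows named for their differences. It changed by -1.53 kb in wt and by 15.6 kb in HDAC3 KO at chromosome 1, 193050001 to 193100000, and after division by total covered length by -2.70 and 6.43 kb. It changed by 0.48 kb in wt and by -11.8 kb in HDAC3 KO at chromosome 2, 167750001 to 167800000, where after that division the sign in wt turned, at -0.13 kb, with -15.2 kb in HDAC3 KO. It changed by 4.16 kb in wt and by -5.97 kb in HDAC3 KO at chromosome 9, 114650001 to 114700000, and by 3.94 and -9.82 kb after division.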

How the results depend on the processing

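All counts of windows and of wide peaks, the alternative counts of regions by the libraries that called them, the stricter calls and the joined peaks were chosen after seeing the data. So were the score thresholds of 100, 200, 500 and 1000, and the other alternatives were chosen before. With 1 library per group no paired or leave-one-out analysis was possible, and the planned promoter and gene-list alternatives were not run, since the gene table was on another build. Values with no test were taken to have moved when they left the counting interval or, for a count, length or width, by over 1.5 times. Correlations were judged by a fixed difference. By these measures 27 of the values answering a comparison stayed and 81 moved. Some had to move, such as peak numbers at or above each list's median score, so the tally does not measure robustness. Unknown depth limits all of them: a region without a call was not shown to lack acetylation. Apart from fewer peaks under stricter scores and a wider or narrower overlap, the cause of each change was not tested.

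The share of peaks without a partner, given in pairs, was as follows. With peaks at or above the median score it was 28.8 (LPS-treated) and 34.5% (untreated) in wt, 35.7 and 23.4% in HDAC3 KO, 19.0 (HDAC3 KO) and 25.4% (wt) untreated, and 29.2 and 15.5% with LPS. With the 20000 highest-scored peaks it was 34.9 (LPS-treated) and 28.6% (untreated) in wt, 33.3 and 26.3% in HDAC3 KO, 24.5 (HDAC3 KO) and 20.9% (wt) untreated, and 24.2 and 20.0% with LPS, which turned the order in wt and between untreated genotypes. With an overlap of at least 50% of the peak it was 40.0 (LPS-treated) and 40.8% (untreated) in wt, 49.1 and 29.4% in HDAC3 KO, 32.3 (HDAC3 KO) and 34.3% (wt) untreated, and 43.0 and 22.5% with LPS. With peaks within 500 bp counted as shared it was 25.3 (LPS-treated) and 28.4% (untreated) in wt, 33.5 and 19.0% in HDAC3 KO, 16.7 (HDAC3 KO) and 22.1% (wt) untreated, and 27.9 and 14.6% with LPS. Leaving out the X, Y and unplaced sequences kept every share within its interval.

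In the crossed design, the shares of wt-gained regions with a peak in LPS-treated HDAC3 KO, of wt-lost regions without one there and of wt-gained regions with a peak in untreated HDAC3 KO follow in that order. They were 61.6, 71.1 and 14.2% at or above the median score, 56.2, 74.1 and 19.2% with the 20000 highest-scored peaks, 51.6, 71.0 and 13.2% with regions merged across 500 bp and 69.6, 77.0 and 4.06% with the stricter calls. Regions called in both LPS-treated, both untreated, both HDAC3 KO and both wt libraries alone numbered 2345, 2067, 764 and 578 at or above the median score, 2408, 1727, 729 and 561 with 20000 peaks, 2468, 2191, 1108 and 1008 with merged gaps and 984, 467, 165 and 116 with the stricter calls.

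In the order untreated wt, LPS-treated wt, untreated HDAC3 KO and LPS-treated HDAC3 KO, peaks numbered 24353, 19790, 20997 and 22795 at or above the median score, 14984, 15662, 13773 and 18400 at a score of at least 200 and 4046, 7139, 4150 and 8359 at 500. Joining peaks within 500 bp left 32129, 27387, 28087 and 30686. Peaks of at least 3000 bp numbered 191, 823, 443 and 1685. Median widths at or above the median score in the last 3 of these libraries were 1141.5, 1048.0 and 1325.0 bp.

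Windows that gained at least 5000 bp in both genotypes numbered 192 after division by total covered length. Windows that lost as much in both numbered 80 after that division, 59 with 100-kb windows, 18 at or above the median score and 15 with 20000 peaks.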

Other observations

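The tests of missed calls and of a single linked segment given here, and all groups of wide peaks and crowded windows, were chosen only after the data were seen; the other tests were written down before their results were seen.

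Broad acetylated domains were more frequent in the LPS-treated lists. Peaks of at least 5000 bp numbered 9 in untreated wt, 148 in LPS-treated wt, 51 in untreated HDAC3 KO and 343 in LPS-treated HDAC3 KO. Most of them lay on positions already called before LPS: of those in LPS-treated wt, 98.7% touched a peak of untreated wt, and a median of 70.4% of their length was covered there. In HDAC3 KO the same values were 95.9 and 68.1%. The widest in LPS-treated wt spanned 13875 bp at chromosome 9, 55943298 to 55957172, of which 8799 bp were covered in untreated wt. The widest in LPS-treated HDAC3 KO spanned 13835 bp at chromosome 14, 63740087 to 63753921, of which 13639 bp were covered in untreated HDAC3 KO. The second widest there, at chromosome 14, 26278790 to 26292181, spanned 13392 bp. Of these, 5291 bp were covered in LPS-treated wt, 9988 bp in untreated wt and 11897 bp in untreated HDAC3 KO. It was chosen for its width in HDAC3 KO, so coverage in wt could only be equal or lower. At the others of the 4 widest, LPS-treated wt covered 11895 of 13835, 11633 of 12860 and 12458 of 12814 bp.

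Regions gained with LPS in both genotypes were crowded on some chromosome segments. Between 80 and 85 Mb of chromosome 16 they were 19 of 54 merged regions (35.2%, exact interval 22.7 to 49.4%), against 6.56% genome-wide. Regions lost in both were 38 of 182 (20.9%, 15.2 to 27.5%) between 5 and 10 Mb of chromosome 17, against 4.86% genome-wide. These were the highest shares among 407 segments of 5 Mb, so a high value is partly the result of choosing.

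LPS changes in covered length went together in the genotypes across 50-kb windows. More called length in the LPS-treated libraries is argued against as the whole cause, since Pearson's r was still 0.67 after each library was divided by its total. The genotype change in untreated and LPS-treated cells had an r of 0.41, and of 0.34 after that division. A genotype difference present under both treatments would also give such an r, so it is not a chance level for the 0.67. How much of the 0.67 would arise without an LPS effect was not measured. For greater variation in windows with more peaks, Spearman rho was computed within 10 groups of windows ordered by mean covered length. Its median was 0.46, from 0.05 to 0.71, against a median of 0.20 for the genotype change in untreated and LPS-treated cells. Mean covered length was therefore not the whole source of the correlation. Variation without a shared direction gives no such correlation, so these values cannot decide that explanation. A response to LPS common to both genotypes may account for the shared changes, as a hypothesis found and tested on the same data. A preparation shared by the libraries of a treatment was not tested, since the labels give no batch.

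Regions called in both libraries of a single genotype numbered 3012, of which 90 scored at least 200 in each library. For the 90, calls missed by chance are argued against as the main source, since only 2 regions with such scores were called in exactly a pair of libraries that differed in genotype and treatment. Over regions of any score such pairs held 1455, a ratio of 0.48 to the 3012, so for the weaker regions missed calls stay open. A single linked segment from another strain is argued against as the source of most of the 90, since the chromosome with the most, chromosome 11, held 12 (13.3%, exact interval 7.08 to 22.1%), whereas smaller strain segments stay open for part of them: the most crowded 5-Mb segment, 75 to 80 Mb of chromosome 15, held 4, and a share of 0.144 of 10000 random draws held as many (median 3). A lasting effect of HDAC3 may account for some of the 90 regions and stays untested.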
